A study of Mus musculus with 8 samples.

How the data were processed

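Ribosome-associated mRNA was sequenced from 8 mouse spinal cords. The mice carried an HA-tagged Rpl22, a protein of the large ribosomal subunit, whose tag is switched on by Cre recombinase, and tagged ribosomes were precipitated with an antibody against HA. Chat-Cre places the tag in cholinergic cells, which in the spinal cord include the motor neurons. Mice without Cre served as negative controls for mRNA that comes down without the tag. The deposited gene tables were made by the authors with Bowtie2 2.2.0 and RSEM 1.2.12, and their expected counts per gene were used here. Expected counts are estimates of reads per gene, not scaled for depth or gene length, and were rounded to whole numbers. The deposited column of gene lengths, in bases as RSEM writes it and of the type other, was not used here. The genome build and annotation are not given in the sources used here, so no coordinates are printed. Gene symbols were assigned to 37607 of the 38924 Ensembl gene identifiers (96.6%) through a table of identifiers and symbols.

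Libraries were grouped by their titles into Cre crushed, no-Cre crushed, Cre uncrushed and no-Cre uncrushed, with 2 animals in each of the 4 groups. The genotype entry contradicted the title for Cre uncrushed animal 3 and no-Cre uncrushed animal 4. Levels of motor neuron mRNAs were checked in every library, and no library was moved between groups. No paired analysis was possible because no animal number occurred in more than 1 group. The crushed mice were 9 or 18 weeks old and the uncrushed mice 8 weeks, so crush could not be separated from age. The titles of all uncrushed libraries also share a number that no crushed title carries. Its meaning is not given, and crush could not be separated from it either. Library totals ran from 4826979 to 11522721 expected counts. With these totals and the scaling factors, 3 counts corresponded to between 0.19 and 1.17 CPM. Intervals and floors from counts cover counting error only.

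Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 15208 genes, and libraries were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 8 libraries (4 residual degrees of freedom). Comparisons were the crush effect with Cre, the crush effect without Cre, their difference (the interaction), and Cre against no-Cre in uncrushed libraries, in crushed libraries and, with crush as a covariate, in all libraries. All tests were two-sided. Genes were called at a Benjamini-Hochberg adjusted p of 0.05. Values after ± are approximate standard errors for log2 fold changes and standard deviations for levels, with n = 2 animals per group. The former are the log2 fold change divided by the square root of the F statistic of its test. Where a group holds few counts they are not a reliable measure of precision. CPM values use TMM-scaled totals. A fold against a group with 1 to 3 counts is given as a ratio with its exact 95% Clopper-Pearson interval, and one against a group at 0 as a bound at 3 counts over the group.

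Gene lists for cell types, injury, stress, metabolism and mitochondria (26 in all) were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists within a comparison. The same tests were repeated with an estimated correlation and with fry. Of 539 symbols in the lists, 537 were found, 2 of them through synonyms, and Slc18a3 and Lhfpl3 were not matched and not tested. The lists, groups, comparisons, alternatives and the rule for named genes were fixed before the data were examined. The rule named a fixed set of marker and injury genes in every comparison, then the 10 called genes with the smallest p in each direction, leaving out predicted or unnamed genes, and up to 4 members per list with a mean of at least 1 CPM.

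The alternatives were DESeq2 1.42.0 with its Wald test, its size factors in edgeR, scaling by library size alone, no filter on low counts, a fit of only the compared groups, grouping by the genotype entry, leaving out both libraries with contradictory entries, age as a covariate, and leaving out each library in turn. Within groups age differed only between Cre crushed animals 35 (18 weeks) and 52 (9 weeks). The age covariate therefore chiefly sets these 2 libraries apart and cannot separate age from crush. The scripts were tested on simulated data made from the libraries, with 200 changed genes. For crush with Cre, on 15198 genes, the fit of all libraries recovered 99 of the 200 (49.5%) with 0 false calls, at 6% of genes with a 2-fold change, 67.2% at 4-fold and 75.8% at 8-fold. For crush without Cre, on 15319 genes, it recovered 106 but 37 of its 143 calls were false. A fit of only the no-Cre groups, on 13443 genes, made 94 calls with 3 false.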

Results

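The series asked which mRNAs were bound to ribosomes in motor neurons after crush of the sciatic nerve on 1 side. Tagged ribosomes were precipitated from whole spinal cord of 2 mice with Cre and a crushed nerve (animals 35 and 52), 2 without Cre and with a crushed nerve (51 and 58), 2 with Cre and no crush (10 and 3) and 2 with neither (4 and 6). The time between crush and tissue collection is not given in the sources used here. Totals were 11522721 and 9401129 expected counts in the Cre crushed libraries, 8215026 and 9609300 in the Cre uncrushed libraries, 4826979 and 6468110 in the no-Cre crushed libraries, and 4903056 and 5203850 in the no-Cre uncrushed libraries. Mitochondrial ribosomal RNA took 3.146 ± 2.168% of counts in the Cre crushed and 3.928 ± 2.267% in the Cre uncrushed libraries, against 25.69 ± 20.11% and 40.46 ± 10.97% in the no-Cre crushed and uncrushed libraries. Libraries of the same group correlated across genes at a Pearson r of 0.962 to 0.974 with Cre and 0.869 to 0.927 without, where genes are not independent replicates. The biological coefficient of variation was 0.209 among Cre and 0.339 among no-Cre libraries.

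Motor neuron mRNAs separated the libraries by title. Chat, the enzyme that makes acetylcholine, stood at 97.7 and 126.02 CPM in Cre uncrushed animals 10 and 3, and at 4.29 and 4.81 CPM in no-Cre uncrushed animals 4 and 6. Slc5a7, the high-affinity choline transporter, stood at 529.89 and 574.4 CPM against 31.19 and 28.85 CPM, and Prph, the intermediate filament peripherin, at 556.82 and 564.07 CPM against 83.83 and 56.09 CPM. Mnx1, a motor neuron transcription factor, had 17.82 and 15.68 CPM in the Cre uncrushed libraries and 0 counts in both no-Cre uncrushed ones. Isl1, another such factor, stood at 11.45 and 11.78 CPM with Cre, and at 10.14 CPM in no-Cre animal 4 and 2.94 CPM in animal 6 (adjusted p = 0.300). The 2 libraries with a contradictory genotype entry therefore held the Chat, Slc5a7, Prph and Mnx1 levels of their titles. Isl1 did not separate them. Rpl22, the gene that carries the tag, was at 34.7 ± 6.5 CPM with Cre and 28.8 ± 1.12 CPM without.

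Cre against no-Cre in uncrushed mice asked which mRNAs the tag enriches in resting cholinergic cells. Genes of cholinergic and motor neurons were higher with Cre, and genes of glia, vessels and interneurons were lower. Chat (ENSMUSG00000021919) was 24.4-fold higher (log2 4.61 ± 0.30, adjusted p = 2.44e-05) and Slc5a7 (ENSMUSG00000023945) 18.4-fold higher (4.20 ± 0.30). Chodl, a marker of fast motor neurons, was higher by 4.64 ± 0.34 on the log2 scale, Slc10a4, a vesicular protein of cholinergic neurons, by 4.78 ± 0.37, and Prph by 3.01 ± 0.44. Rspo2, a secreted Wnt agonist (5.79 ± 0.39), Pdgfd, a growth factor (3.92), Plxdc1 (3.83), Hspb8, a small heat shock protein (3.56), Bcl6, a transcriptional repressor (3.31), Mcam, an adhesion molecule (3.31), and Nell2, a secreted neuronal protein (3.28), were the other named genes with the smallest p. The named lower genes were Leng8 (-3.55 ± 0.25), Car2, a carbonic anhydrase of oligodendrocytes (-3.66), Aspa, a myelin-forming cell enzyme (-3.72), Ermn, a myelin protein (-3.70), Neat1, a nuclear non-coding RNA (-3.48), Padi2 (-3.35), Epas1, a hypoxia-inducible factor (-3.22), Myo10 (-3.18) and Ttyh1 (-2.97). In all, 3137 genes were called higher and 3331 lower of 15208. Scaling by library size alone raised the median log2 fold change of all genes by 0.68 and turned the split into 4753 higher and 1463 lower. Without the 2 libraries with contradictory entries 3299 genes were called, and without Cre uncrushed animal 3 alone 3802.

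The lists fixed in advance described the same comparison by group. Of 25 cholinergic motor neuron markers tested, 22 were called higher and 1 lower (23 and 1 adjusted over the list alone), with a median log2 fold change of 3.15 (camera adjusted p = 1.24e-11). Of 15 pan-neuronal genes 12 were higher (median 1.55, adjusted p = 1.58e-05), with Tubb3, a neuronal tubulin, at 2.68 ± 0.27. All 16 oligodendrocyte markers (median -3.08, Mbp -3.23 ± 0.34), all 14 astrocyte markers (-3.06, Gfap -3.04 ± 0.30), 16 of 19 microglia and macrophage markers (-3.23, Cx3cr1 -3.67, Aif1 -3.60, the latter not called without Cre uncrushed animal 10 or 3 at adjusted p = 0.0553 and 0.0861) and 12 of 14 endothelial and pericyte markers (-2.90) were called lower. Lower calls were also made for 12 of 20 interneuron markers (-1.92, with the glycine transporter Slc6a5 at -2.13), 7 of 10 meningeal fibroblast markers (-2.77), 11 of 12 blood cell markers (-2.71), 7 of 9 Schwann cell markers (-3.25), 6 of 9 oligodendrocyte precursor markers with 1 higher (-2.48), and 3 of 8 sensory ganglion neuron markers (-3.04). Among the metabolic lists, 19 of 22 nuclear oxidative phosphorylation genes were higher (1.33, Atp5o 2.2 ± 0.29), 13 of 20 cholesterol biosynthesis genes were higher and 1 lower (1.07), and all 13 mitochondrially encoded genes were lower (-3.08, mt-Nd3 -3.32 ± 0.39). Genes for making and folding protein were higher for 12 of 21 cytosolic tRNA synthetases (1.05, Nars 2.02, Gars 1.40 ± 0.32), 8 of 19 chaperones (0.98, Hspa8 2.35) and 27 of 75 ribosomal proteins (0.70). Of 34 receptors and channels 14 were higher and 6 lower (0.49, with the muscarinic receptor Chrm2 at 2.65), of 15 antigen presentation and complement genes 1 was higher and 8 lower (-2.10). Of 11 interferon-stimulated genes 4 were lower (-1.29). By camera with a preset correlation 9 lists were called higher and 13 lower, and with an estimated correlation 0 were called (for motor neuron markers adjusted p = 0.139). fry, which asks whether a list moves on balance in 1 direction and does not compare it with other genes, called 20.

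**Figure D1:**
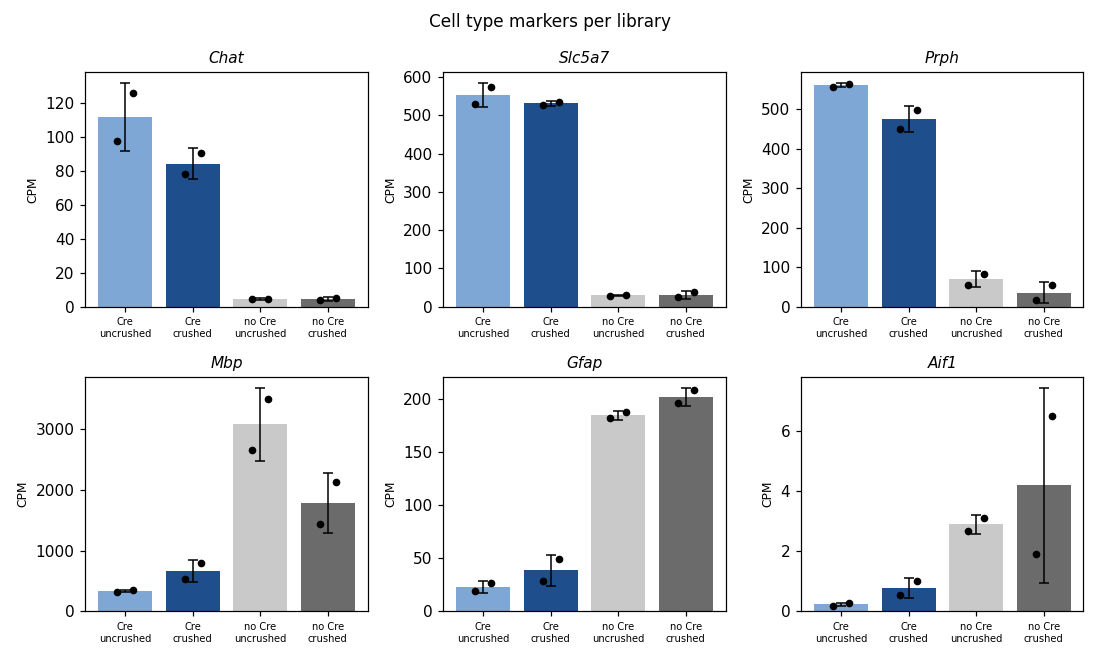
Levels in CPM, on axes that start at 0, of Chat, Slc5a7, Prph, Mbp, Gfap and Aif1 in the 4 groups, where bars are means, error bars are standard deviations and points are the 2 libraries of each group. Chat stands at 84.5 and 112 CPM in the Cre crushed and uncrushed groups and at 4.49 and 4.55 CPM in the no-Cre groups, and Mbp at 665 and 330 CPM with Cre against 1790 and 3080 CPM without.

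Cre against no-Cre in crushed mice asked the same question after injury. Motor neuron genes again stood out, together with genes known from injured axons. Chodl was higher by 5.23 ± 0.34 on the log2 scale (adjusted p = 2.58e-05), Chat by 4.22 ± 0.28, Slc5a7 by 4.08 ± 0.29 and Prph by 3.74 ± 0.45. Lgals1, a secreted galectin of growing axons, was higher by 5.11 ± 0.33, and S100a10 by 4.11 ± 0.34. The co-chaperone Bag3 (3.65) and its partner Hspb8 (3.62), the potassium channel Kcnj14 (3.82), the nuclease inhibitor Dffa (3.52), Anxa6 (3.42) and Pdgfd (3.35) were the other named genes. The injury genes Sprr1a (3.89 ± 0.40), Atf3 (3.73 ± 0.50), Gal (2.90 ± 0.56), Jun (2.00 ± 0.28) and Gap43 (1.63 ± 0.33) were all called higher with Cre, and Npy stood at 2.92 ± 0.57. Jun also stood higher with Cre in uncrushed mice, at 94.71 and 84.24 CPM against 33.14 and 21.63 CPM without. The same held for S100a10, at 81.7 and 74.31 CPM against 7.8 and 5.88 CPM. Lgals1 likewise stood at 135.69 and 131.47 CPM with Cre in uncrushed mice, against 7.8 and 5.88 CPM without. The named lower genes were Hsf2 (-5.32 ± 0.42, 4280 ± 1340 CPM without Cre), Zc3h10 (-4.88), mt-Nd3 (-4.52), Cx3cr1, the microglial fractalkine receptor (-4.06), Spaca6 (-3.97), Ptgds (-3.60), Vtn (-3.52), Noc2l (-3.44), Aspa (-3.36) and Nid1 (-2.76). Mbp (-1.43 ± 0.32), Gfap (-2.39 ± 0.29) and Aif1 (-2.38 ± 0.80) were called lower, Gars was higher by 1.90 ± 0.32, and Rpl22 was not called (0.43 ± 0.27). Aif1 lost its call without Cre crushed animal 35 (-2.84, adjusted p = 0.126), Cre crushed animal 52 (-1.98, 0.192) or no-Cre crushed animal 58 (-1.21, 0.396). Without animal 35 Mbp (-1.13, 0.0935) and Npy (2.33, 0.0671) lost theirs. In all, 3286 genes were called higher and 3235 lower, and scaling by library size shifted the median by 0.14 and the share of calls that were higher from 50.4% to 59.6%. Age as a covariate, which within groups differs only between animals 35 and 52, left 2758 calls. Leaving out a Cre animal, whichever it was, or either no-Cre crushed animal also lowered the number of calls, most of all without animal 35.

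By list, 21 of 25 motor neuron markers were called higher in crushed mice (median 3.11, camera adjusted p = 3.96e-13), as were 12 of 15 pan-neuronal genes with 1 lower (1.91, Tubb3 3.59 ± 0.28) and 24 of 39 axon injury and regeneration-associated genes with 5 lower (1.63, adjusted p = 3.29e-06). In uncrushed mice 15 of those 39 injury genes had been higher and 8 lower (0.55, adjusted p = 0.022, not called with an estimated correlation), with Lgals1 at 4.31 ± 0.33. All 16 oligodendrocyte markers (-2.33), 13 of 14 astrocyte markers (-2.48), 14 of 19 microglia markers (-2.38), 13 of 14 endothelial markers (-2.49), 8 of 9 oligodendrocyte precursor markers with 1 higher (-2.31), 5 of 9 Schwann cell markers (-1.91) and 10 of 12 blood cell markers (-3.15) were lower with Cre. Of 20 interneuron markers 7 were lower, Slc6a5 among them at -1.45, and 1, Npy, was higher. Oxidative phosphorylation genes were higher for 20 of 22 (1.67, Atp5o 2.46), ribosomal protein genes for 42 of 75 (0.93, Rpl29 2.15), tRNA synthetases for 16 of 21 (median 1.2, Sars 1.76) and cholesterol genes for 14 of 20 with 1 lower (1.00), while all 13 mitochondrially encoded genes were lower (-3.83). With an estimated correlation 0 of the 19 calls remained (for injury genes adjusted p = 0.195), and fry called 21 lists.

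Over all 8 libraries, with crush as a covariate, 4364 genes were called higher and 4738 lower with Cre, 59.9% of those tested. The smallest p belonged to Chat (4.39 ± 0.21, adjusted p = 1.15e-07), Slc5a7 (4.14 ± 0.20), Hspb8 (3.59), Chodl (4.94), Slc10a4 (4.72), Bag3 (3.55), Anxa6 (3.37), Mcam (3.23), Pdgfd (3.59) and Lgals1 (4.73). In the other direction they were Aspa (-3.53), Ptgds, the prostaglandin D synthase of meninges and oligodendrocytes (-3.70), Vtn (-3.62), Spaca6 (-4.26), Tmbim1 (-2.91), Nid1, a basement membrane protein (-2.75), Zbtb20 (-2.71), Gas7 (-2.53), Rassf2 (-2.54) and Tmem229a (-2.16). Of the genes called in uncrushed and in crushed mice, 2504 were higher in both, where independent lists would share 678, and 2386 were lower in both, where they would share 709. In opposite directions 9 genes were called. The log2 fold changes of the comparisons correlated across the 15208 genes at Pearson r = 0.77 and Spearman rho = 0.843.

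Crush against no crush in the Cre libraries asked what injury does to motor neuron mRNA on ribosomes. Since whole cord was taken after a crush on 1 side, its values average over injured and uninjured motor neurons. A small set of genes rose, with Sprr1a, Atf3 and Npy among them on the list of axon injury genes. Sprr1a (ENSMUSG00000050359), a small proline-rich protein of regenerating axons, rose 557-fold, from 0.276 ± 0.0226 to 163 ± 42.8 CPM. Its log2 fold change was 9.12 ± 0.58 (adjusted p = 6.83e-05), and it was higher in both crushed libraries than in either uncrushed one. The uncrushed libraries held 2 (animal 10) and 3 (animal 3) counts of it, so the size of the fold is imprecise. Atf3 (ENSMUSG00000026628), a stress-induced transcription factor, rose from 2 to 1266 counts over the group, a ratio of 400 (95% interval 110 to 3300) and a fitted log2 fold change of 8.42 ± 0.73 (adjusted p = 0.000618). Npy, neuropeptide Y, rose by 4.85 ± 0.66 to 11.6 ± 5.73 CPM (adjusted p = 0.0213). Ccl7, a chemokine that attracts monocytes, had 276 counts after crush and 0 before, at least 58.1-fold higher (adjusted p = 0.0213). Serpinb1a, a protease inhibitor, rose by 3.80 ± 0.45 (adjusted p = 0.00876), and Leng8 by 1.93 ± 0.24 from 13.8 to 52.6 CPM (adjusted p = 0.0115). Leng8 stood at 169 ± 23.4 CPM in the no-Cre crushed libraries, and in crushed mice it was lower with Cre than without (-1.68, adjusted p = 0.000319). The sensory ganglion neuron marker Scn10a, chosen after its values were seen, stood at 5.76 CPM in Cre crushed animal 35 and 0.08 CPM in animal 52, where Sprr1a stood at 193.49 and 132.99 CPM and Npy at 15.7 and 7.6 CPM.

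Genes that fell were Grin2b, an NMDA receptor subunit, by 1.64 ± 0.22 on the log2 scale from 321 to 103 CPM (adjusted p = 0.0213), and mt-Nd3, a mitochondrially encoded subunit of complex I, by 2.72 ± 0.38 (adjusted p = 0.0243). The other 3 genes that fell, Gm26582 (-4.52, adjusted p = 0.000556), Gm10052 (0 in both crushed libraries, 35.13 and 16.36 CPM in the uncrushed ones) and Rpl15-ps2 (-5.80, adjusted p = 0.0402), are predicted genes or pseudogenes and were chosen after their values were seen. Galanin, Gal, stood at 22.9 against 2.08 CPM (3.49 ± 0.57, adjusted p = 0.0783) and Gap43, a growth cone protein, at 119 against 50.3 CPM (1.25 ± 0.33, adjusted p = 0.228), short of the threshold. Motor neuron identity genes were not called, with Chat at -0.40 ± 0.23 (adjusted p = 0.659), Slc5a7 at -0.06 ± 0.25 and Prph at -0.24 ± 0.40. The values of Jun (-0.13 ± 0.27), Atf4 (-0.50 ± 0.32), Gars (0.04 ± 0.30) and Rpl22 (-0.26 ± 0.27) did not pass the test either. In all, 6 genes were called higher and 5 lower, with 1421 at an unadjusted p under 0.05 where 760 would be expected by chance. A fit of the Cre libraries alone called 49 higher and 77 lower of 13808 genes, including all 11, and DESeq2 called 159. With the 2 contradictory libraries left out 5 of the 11 remained, with age as a covariate 3, and without any 1 of the 4 Cre animals (35, 52, 10 or 3) there were 7 calls. Sprr1a, Atf3, Gm26582 and Gm10052 kept their calls whichever library was left out.

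**Figure D2:**
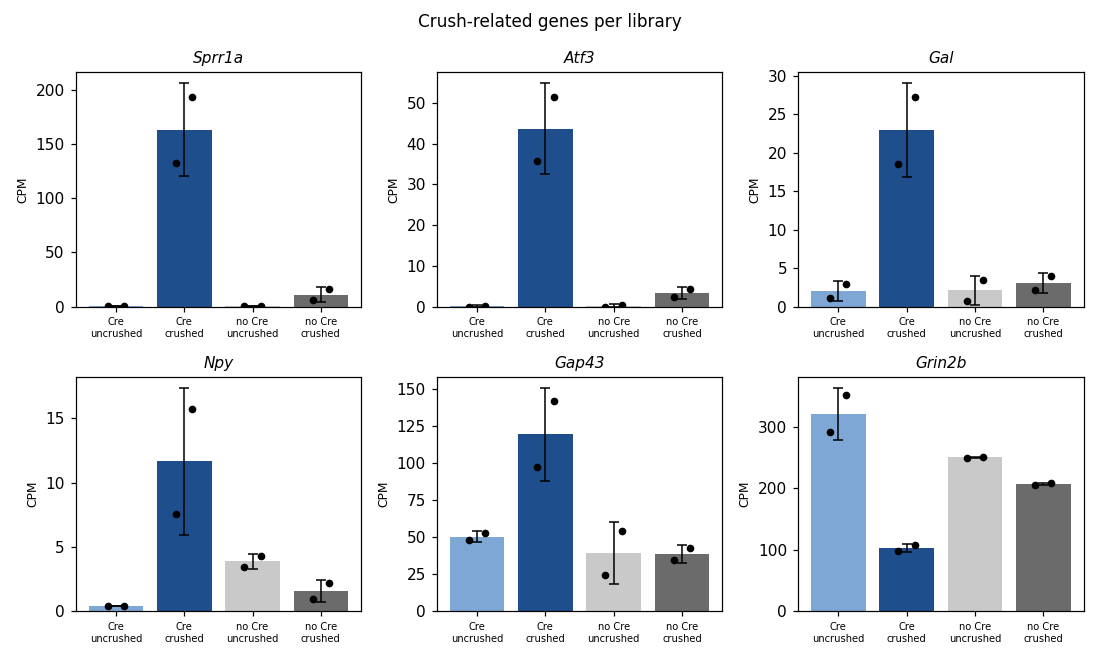
Levels in CPM, on axes that start at 0, of Sprr1a, Atf3, Gal, Npy, Gap43 and Grin2b in the 4 groups, where bars are means, error bars are standard deviations and points are the 2 libraries of each group. Sprr1a stands at 163 CPM in the Cre crushed group, 11.1 CPM in the no-Cre crushed group and 0.276 CPM in the Cre uncrushed group, and Grin2b falls from 321 to 103 CPM with Cre.

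Among the lists, 3 of 39 axon injury and regeneration-associated genes, Sprr1a, Atf3 and Npy, were called higher after crush with Cre (9 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 0.000242, and adjusted p = 0.383 with an estimated correlation). In the fit of the Cre libraries alone 8 of the 37 tested there were higher, namely Sprr1a, Atf3, Npy, Gal, Gap43, Chl1, Cd44 and Ankrd1, of which the last 3 were chosen after their values were seen. Mitochondrially encoded mRNAs were lower as a group, with 1 of 13 called over all genes and 13 adjusted over the list alone (median -2.34, adjusted p = 3.88e-24, and 0.313 with an estimated correlation), among them mt-Co2 at -2.34 ± 0.43 and mt-Atp8 at -2.77 ± 0.46. The fit of the Cre libraries alone called 6 of the 13 lower, mt-Nd3, mt-Co2 and mt-Atp8 among them. Their share of counts was 0.843 ± 0.2729% after crush and 2.386 ± 1.034% before. Neurotransmitter receptors and channels were called lower by camera (adjusted p = 0.0245, and 0.639 with an estimated correlation) at a median of -0.03 over 34 genes, of which Grin2b alone was called, with Kcna2 at -0.67 ± 0.26 and Glrb at -0.56 ± 0.23. The 25 motor neuron markers were called lower as a group (median -0.27, adjusted p = 0.0303, and 0.632 with an estimated correlation) with 0 members called, Nefh at -0.87 ± 0.35 and Gfra1, a receptor for GDNF, at 0.79 ± 0.31. Without Cre crushed animal 52 or Cre uncrushed animal 3, motor neuron markers (adjusted p = 0.163 and 0.148) and receptors and channels (0.0799 and 0.345) were not called.

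Markers of other cell types moved with crush in the Cre precipitates. In the fit of all libraries no member was called over all genes, but 10 of 16 oligodendrocyte markers were called higher adjusted over the list alone (median 0.90, camera adjusted p = 2.4e-10, and 0.382 with an estimated correlation), with Mobp at 1.52 ± 0.30, Trf at 1.44 ± 0.26 and Mbp at 1.01 ± 0.32. Of 14 astrocyte markers 7 were higher adjusted over the list alone (median 0.81, adjusted p = 1.83e-07, and 0.313 with an estimated correlation), with Aqp4 at 1.19 ± 0.31, Slc1a2 at 1.09 ± 0.33 and Gfap at 0.78 ± 0.29. In the fit of the Cre libraries alone Trf (adjusted p = 0.038), Mobp and Aqp4 (both 0.0449) and Slc1a2 (0.048) were called higher over all genes. That fit called 0 of 11 microglia and macrophage markers and 0 of 12 endothelial and pericyte markers. In the fit of all libraries, adjusted over the list alone, 1 of 19 microglia and macrophage markers was higher (0.92, adjusted p = 0.000242, estimated 0.313, Ctss 1.82 ± 0.41, Csf1r 1.71 ± 0.60, Aif1 1.75 ± 0.97). For endothelium and pericytes 2 of 14 were higher in the same way (0.95, adjusted p = 0.000242, estimated 0.382, Flt1 1.58 ± 0.35, Cdh5 2.28 ± 0.63). Oligodendrocyte precursor markers (0.88, adjusted p = 0.0241, Pdgfra 1.97 ± 0.50), Schwann cell markers (0.79, adjusted p = 0.019) and antigen presentation and complement genes (0.68, adjusted p = 0.00887) were also higher, each with adjusted p = 0.383 at an estimated correlation. Precursor markers were not called without Cre crushed animal 52 (adjusted p = 0.102) or Cre uncrushed animal 3 (0.0995). Schwann cell markers were not called without Cre crushed animal 35 (0.0567) or Cre uncrushed animal 3 (0.127). Antigen presentation genes were not called without Cre uncrushed animal 3 (0.068). Mbp stayed below its no-Cre level, at 665 ± 184 CPM in the Cre crushed and 1790 ± 492 CPM in the no-Cre crushed libraries. Under grouping by the genotype entry the medians of these cell type lists were negative.

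The remaining lists were not called for crush with Cre. Their medians and camera adjusted p were -0.03 and 0.3 for integrated stress response and ATF4 target genes, 0.04 and 0.992 for cytosolic tRNA synthetases, -0.13 and 0.116 for unfolded protein response genes and chaperones, -0.08 and 0.278 for pan-neuronal genes, and 0.24 and 0.0584 for interneuron markers. Sensory ganglion neuron markers had 0.28 and 0.992, meningeal fibroblast markers 0.33 and 0.149, ependymal markers 0.27 and 0.41, blood cell markers -0.15 and 0.212, and cholesterol biosynthesis genes 0.17 and 0.337. Interferon-stimulated genes had 0.54 and 0.0584, cell cycle genes -0.19 and 0.447, nuclear oxidative phosphorylation genes -0.28 and 0.0584, and cytosolic ribosomal protein genes -0.16 and 0.0532. Immediate early genes had a median of -0.38 and a mean of 0.25, of opposite sign, and adjusted p = 0.475, with Atf3 the 1 member called.

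Crush against no crush in the no-Cre libraries measured the background. Sprr1a was higher there too, with 142 counts after crush and 2 before, a ratio of 33.5 (95% interval 9.1 to 279, adjusted p = 0.0486). Its level was 11.1 ± 7.11 CPM, against 163 CPM with Cre, and stood at 6.11 CPM in animal 51 and 16.16 CPM in animal 58, where Scn10a stood at 0.14 and 11.66 CPM. Atf3 had 43 and 2 counts, a ratio of 10.1 (2.64 to 86.4), and was not called (adjusted p = 0.297). Cep350, a centrosomal protein, fell by 3.03 ± 0.33 from 1490 ± 691 to 182 ± 18 CPM (adjusted p = 0.0187), while Dbn1, an actin-binding protein of dendrites (-1.70 ± 0.23), Myh9, a non-muscle myosin (-1.96 ± 0.29), and Tax1bp1 (-1.80 ± 0.27) fell and Zc3h10 rose (2.56 ± 0.37), all at an adjusted p of 0.0486. The other 5 calls, chosen after their values were seen, were Gm26582 (-2.23), G530011O06Rik (-2.63), ENSMUSG00000085119 (5.38), and Gm10052 and Gm47283, which were at 0 in both crushed libraries. Gal (0.41 ± 0.68), Gap43 (-0.04 ± 0.34), Chat (-0.02 ± 0.34), Slc5a7 (0.06 ± 0.27), Prph (-0.97 ± 0.42), Mbp (-0.79 ± 0.31) and Gfap (0.13 ± 0.28) were not called. In all, 3 genes were called higher and 8 lower, with 1941 at an unadjusted p under 0.05. In the simulated data 37 of 143 such calls were false, and a fit of the no-Cre libraries alone called 2 genes. Leaving out no-Cre crushed animal 58, Cre uncrushed animal 10 or Cre uncrushed animal 3 ended every call. Library size scaling, which raised the median of all genes by 0.96, gave 1199 higher and 5 lower. Pan-neuronal genes (median -0.34, adjusted p = 0.00458), nuclear oxidative phosphorylation genes (-0.43, 0.00186), mitochondrially encoded genes (-1.55, 4.99e-12) and ribosomal protein genes (-0.40, 4.75e-08) were lower as groups, each with adjusted p = 0.748 at an estimated correlation.

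The interaction asked whether crush acted differently with Cre. By edgeR's quasi-likelihood test no gene was called (smallest adjusted p = 0.386), with 905 genes at an unadjusted p under 0.05 where 760 would be expected, and DESeq2 called 15. Among the genes read here the differences were 6.17 ± 0.91 for Npy (adjusted p = 0.386), 3.07 ± 0.90 for Gal (adjusted p = 0.816) and 1.80 ± 0.44 for Mbp (adjusted p = 0.806), and Gap43 had 1.28 ± 0.47. For Sprr1a (4.07 ± 1.80) and Atf3 (5.09 ± 1.90), adjusted p was 0.83, and the uncrushed groups held 2 to 5 counts of each. Chat differed by -0.39 ± 0.41. Across 15208 genes the crush effects with and without Cre correlated at Pearson r = 0.218 and Spearman rho = 0.306, where genes are not independent replicates. Sprr1a was called higher and Gm26582 and Gm10052 lower in both genotypes.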

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

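In this part the splits of the libraries were planned, and the tests of the 3 patterns weighed were chosen after the results were seen. For 8 gene lists the camera test of the interaction found a different crush effect with Cre than without, at a preset correlation. The median differences were 0.91 for oligodendrocyte markers (adjusted p = 2.86e-06), 0.53 for axon injury and regeneration-associated genes (adjusted p = 1.99e-05), 0.51 for interneuron markers (adjusted p = 0.000664), 0.27 for cytosolic ribosomal protein genes (adjusted p = 0.000664), 0.52 for astrocyte markers (adjusted p = 0.00638), 0.83 for Schwann cell markers (adjusted p = 0.0115), -0.21 for neurotransmitter receptors and channels (adjusted p = 0.0329) and -0.56 for mitochondrially encoded genes (adjusted p = 0.0343). With an estimated correlation none of these calls remained, at adjusted p = 0.57 or 0.706, and fry called 0. For ribosomal protein genes the medians were -0.16 with Cre and -0.40 without, and for interneuron markers 0.24 and -0.37.

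Over 108 marker genes in 9 lists of non-neuronal cells, the median crush effect was 0.77 with Cre against 0.21 without. With Cre the blood cell (median -0.15), meningeal fibroblast (0.33) and ependymal (0.27) lists were not called, and no list was called with an estimated correlation. With library size scaling, which raises the medians of all genes by 0.44 and 0.96, the medians over the 108 genes were 1.2 against 1.21. A lower share of motor neuron mRNA could raise all of these markers alike. In permutations over genes, the difference of the crush effect with Cre from that without varied between lists (p = 0.00533 over all genes). Over the 88 genes with at least 10 counts in every group the permutation p was 0.00444. Without the ependymal and blood cell lists it was 0.365. These 2 lists were left out because their median differences were negative, so a larger p was likely beforehand and decides nothing. Genes of a list can move together, which permutations over genes ignore. With animals as replicates no list passed a test against the others (smallest Holm-adjusted p = 0.514), so a lower share of motor neuron mRNA stays open. For a rise of non-neuronal mRNA in the whole cord the median difference was 0.53 (SD 1.03 over 108 genes). That SD is the spread between genes and not the error of their median, so it cannot decide the question. The medians of the lists ran from -0.72 for blood cell to 0.91 for oligodendrocyte markers. A rise in the whole cord therefore stays open. Crushed and uncrushed mice shared 0 ages, so age or handling cannot be told apart from crush, and a response of the tagged cells themselves stays open as well.

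Mitochondrially encoded mRNAs were lower after crush with Cre (median -2.34) and without (median -1.55). Neither call of the list remained with an estimated correlation. In the fit of all libraries only mt-Nd3, with Cre, was called over all genes (adjusted p = 0.0243). Scaling by a few abundant genes is argued against for the fall with Cre, since the median was -1.87 with library size and -2.13 with totals that left out Gm42418, Lars2 and mitochondrial ribosomal RNA (SD 0.62 over 13 genes), while without Cre it was -0.60 and -0.97 under these scalings. Fewer mitochondria carried into the crushed precipitates may account for the fall. With Cre, mt-Rnr2 stood at -0.83 ± 0.81 and mt-Rnr1 at -0.72 ± 0.84, above the range of the mRNAs (-2.77 to -1.05) by less than their approximate standard errors. Without Cre they stood at -1.39 ± 0.82 and -1.55 ± 0.86, inside the range of the mRNAs there (-1.99 to -1.09). Fewer mitochondria cannot be told apart from a change in mitochondrial transcripts. Age and handling, confounded with crush, also stay open.

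Sprr1a appeared in the crushed no-Cre precipitates, where no tagged ribosomes are made. A candidate explanation is motor neuron mRNA that comes down without the tag: the Cre against no-Cre log2 ratio of Sprr1a in crushed libraries was 3.89 ± 0.40, inside the range of the 21 called motor neuron markers (1.42 to 5.23, median 3.39). Only markers called higher with Cre set that range, and Sprr1a was itself called higher with Cre, so a place inside the range was likely beforehand. The range therefore cannot tell motor neuron mRNA from that of other cells. Sensory ganglion neurons are another candidate: their marker Scn10a stood at 0.14 and 11.66 CPM in no-Cre crushed animals 51 and 58, and Sprr1a at 6.11 and 16.16 CPM. How much Sprr1a these or other cells gave was not tested and stays open.

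The number of genes called between Cre and no-Cre over all 8 libraries was compared with the other splits into 4 and 4. Of 35 splits only the real one, 1 in all, gave 9102 genes, and the highest other gave 0. Every other split held Cre and no-Cre libraries in both arms, so a large Cre difference widened its spread and lowered its count. The real split thus ranked first, but 1 of 35 is the smallest share these splits can give, and they do not exclude chance.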

How the results depend on the processing

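All alternatives here were planned before the data were examined. With 2 animals per group the tests rest on the spread shared by all groups, and where 1 library was left out the lone library of its group was assumed to vary like the others. Within groups age differed only between Cre crushed animals 35 and 52, so age as a covariate is close to leaving out animal 35 and is no separate check on age. The depth limits genes with few counts, such as Atf3, Ccl7 and Sprr1a in uncrushed libraries. Of 2531 values computed under the alternatives for 160 gene results, 2153 kept their direction and their side of the threshold, 262 lost the call, 44 gained one and 72 changed sign. Grouping by the genotype entry, which mixes libraries with and without motor neuron mRNA, made up much of this. With list results counted as well, it gave 52 changes of sign and 94 lost calls. No value was obtained for the interaction and the comparison of all libraries from a fit of only the compared groups, since both use every group. Unless a cause is named, the cause was not tested.

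For crush with Cre (11 genes) the count was 159 with DESeq2, 281 with no filter on low counts and 126 in the fit of only the compared groups, each including all 11. It was 5 with both libraries with contradictory labels left out and 3 with age as a covariate, all among the 11. DESeq2 size factors gave the same 11, and library size alone gave 11 of which 8 were the same. Leaving out 1 library gave 7 (without any 1 of the 4 Cre animals) to 15 (without no-Cre uncrushed animal 4 or 6). For crush without Cre (11 genes) the count was 107 with DESeq2, 338 with no filter, 1204 with library size only, 2 in the fit of only the compared groups, 1 with size factors, 2 with age and 0 with both contradictory libraries left out, and it ranged from 0 (without no-Cre crushed animal 58 or Cre uncrushed animal 10 or 3) to 7 (without Cre crushed animal 35) when 1 library was left out. For the interaction (0 genes) it was 15 with DESeq2 and 87 with no filter, and 0 in every fit that left out 1 library.

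For Cre against no-Cre the count in uncrushed mice (6468) was 3299 without both contradictory libraries, of which 3037 were among the 6468, and ranged from 3802 (without Cre uncrushed animal 3) to 6512. In crushed mice (6521) it was 2758 with age as a covariate, and ranged from 2733 (without Cre crushed animal 35) to 7392 (without no-Cre uncrushed animal 4), with 4041 without no-Cre crushed animal 51 and 4250 without Cre crushed animal 52. Over all libraries (9102) it ranged from 7633 to 9041. Grouping by the genotype entry gave 0 genes in all 6 comparisons. By construction that grouping places a library with motor neuron mRNA and a library without it in each uncrushed group, and the spread is shared by all groups.

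The number of lists called was 0 with an estimated correlation in all 5 comparisons with list tests (11, 4, 8, 22 and 19 with the preset one), and 0 by fry for both crush effects and the interaction. Without both contradictory libraries it was 7 for crush with Cre and 5 for the interaction. Under grouping by the genotype entry it was 6 for crush with Cre, 15 for crush without Cre, 17 for the interaction and 1 for Cre against no-Cre in uncrushed mice. Leaving out 1 library gave 7 to 15 lists for crush with Cre, 2 to 7 without Cre, 4 to 12 for the interaction, 19 to 22 in uncrushed and 18 to 22 in crushed mice. The correlation of the crush effects (0.218) was 0.086 with no filter, 0.344 in the fits of only the compared groups, 0.16 without both contradictory libraries and -0.26 under the genotype entry, and ranged from 0.106 to 0.188 when 1 library was left out, below the value of the full set in each case.

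Log2 fold changes that changed sign when grouped by the genotype entry were, for crush with Cre, -0.70 for Leng8, 0.34 for Jun, 0.71 for Chat, 0.92 for Slc5a7, 0.56 for Prph, -1.53 for Mbp, -1.42 for Gfap, -0.93 for Aif1, -0.57 for Trf, -0.90 for Mobp, -0.51 for Aqp4, -0.92 for Slc1a2, -0.46 for Ctss, -0.21 for Csf1r, -1.75 for Flt1, -1.60 for Cdh5, 0.09 for Glrb and -0.45 for Pdgfra. For crush without Cre they were -3.27 for Slc5a7 and 0.27 for Mbp, for the interaction -1.80 for Mbp and 4.58 for Chat, and for Cre against no-Cre in uncrushed mice -0.35 for Chat, -0.10 for Slc5a7, -0.12 for Bcl6, -0.20 for Chodl, -0.10 for Mcam, -0.27 for Hspb8, 0.27 for Car2, 0.03 for Neat1, 0.12 for Ermn, -0.27 for Gars, -0.39 for Gap43, 0.07 for Sprr1a, 0.38 for Mbp, 0.01 for Gfap, 0.20 for Aif1, -0.05 for Tubb3, 0.00 for Slc6a5, -0.16 for Hspa8, -0.54 for Chrm2, -0.02 for Atp5o and -0.02 for Nars. List medians that changed sign for crush with Cre were 1.42 for cholinergic motor neuron markers, -0.38 for microglia and macrophage markers, -0.66 for astrocyte markers, -0.78 for oligodendrocyte markers, -0.60 for oligodendrocyte precursor markers, -0.84 for Schwann cell markers, -0.56 for endothelial and pericyte markers, 0.22 for neurotransmitter receptors and voltage-gated channels and -0.22 for antigen presentation and complement.

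With library size only, which shifts the median of all genes upward by 0.44 with Cre and 0.96 without, the sign changed for crush with Cre to 0.31 for Jun, 0.02 for Chat, 0.38 for Slc5a7, 0.20 for Prph and 0.19 for Rpl22, and for crush without Cre to 0.84 for Gap43, 0.97 for Chat and 0.16 for Mbp. In uncrushed mice it changed to 0.47 for Sprr1a. Some values also changed sign with both contradictory libraries left out (0.01 for Slc5a7 with Cre, -0.19 for Gal without Cre, 0.01 for Sprr1a in uncrushed mice), with age as a covariate (-0.08 for Gars with Cre, 0.01 for Chat without Cre), with no filter (0.02 for Chat without Cre) and in the fit of only the compared groups (0.02 for Chat).

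Among named genes called for crush with Cre, Sprr1a, Atf3, Gm26582 and Gm10052 kept their calls when any 1 library was left out. Serpinb1a lost its call without Cre uncrushed animal 3 (adjusted p = 0.0833), and Npy without Cre crushed animal 35 (0.231) or either Cre uncrushed animal (0.169 and 0.24). Grin2b lost its call without any 1 of the 4 Cre animals (adjusted p from 0.0775 to 0.383), and Ccl7 likewise (from 0.102 to 0.181). Leng8 lost its call in 3 of the 8 fits, mt-Nd3 in 5 and Rpl15-ps2 in 6, and Gal gained one without no-Cre uncrushed animal 4 (0.0284) or 6 (0.031).

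For crush without Cre, Sprr1a lost its call in 5 of the 8 fits with 1 library left out (adjusted p from 0.0504 to 0.202), and Dbn1 and Tax1bp1 in all 8. Some genes changed sign over these fits. With Cre, Jun ranged from -0.29 to 0.01, Gars from -0.06 to 0.13, and Slc5a7 from -0.12 to 0.01. Without Cre, Gal ranged from -0.20 to 1.96, Gap43 from -0.50 to 0.69, Chat from -0.25 to 0.17 and Slc5a7 from -0.31 to 0.37. In uncrushed mice Gap43 with Cre against no-Cre ranged from -0.07 to 1.12 (called without no-Cre uncrushed animal 6, adjusted p = 0.0269) and Sprr1a from -0.40 to 0.09.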

Other observations

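Several mRNAs of the no-Cre precipitates were abundant there and scarce with Cre. Hsf2, a heat shock transcription factor, stood at 4280 ± 1340 CPM in no-Cre crushed and 107 ± 13.6 CPM in Cre crushed libraries, and Spaca6 at 256 ± 48.5 against 16.3 ± 1.02 CPM. Malat1, a nuclear RNA, took 3.835 ± 0.8627% and 3.29 ± 0.3974% of counts in no-Cre crushed and uncrushed libraries, against 0.597 ± 0.1796% and 0.4495 ± 0.1619% with Cre. Gm42418, a transcript that overlaps ribosomal RNA sequence, took 20.26 ± 3.804% of counts in Cre uncrushed, 8.507 ± 0.4992% in Cre crushed, 5.304 ± 0.6421% in no-Cre uncrushed and 3.03 ± 0.9214% in no-Cre crushed libraries. Counts assigned to Lars2, the mitochondrial leucyl-tRNA synthetase, took 1.751 ± 0.1768%, 0.833 ± 0.09758%, 0.5005 ± 0.06718% and 0.393 ± 0.09617% in the same order. The shares of Lars2 and Gm42418 ranked the groups alike. Whether the reads counted for Lars2 came from its mRNA was not tested. Gm10052 was at 0 in all 4 crushed libraries and at 6.24 to 35.13 CPM in the uncrushed ones.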
